A study of Mus musculus with 6 samples.

How the data were processed

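Total RNA of mouse cortical neuron cultures, in 6 samples of which 3 were given PBS and 3 PFF, was extracted with a silica column kit and made into libraries with a strand-marking kit, per the labels' protocols. The deposited values are estimated counts per gene, not scaled between libraries: 8.69% of the values were not whole numbers and none was below 0, so the authors' tool assigned fractions of reads. Per the submitters' processing notes, Trim Galore 0.6.6 and STAR 2.7.9a were used with the mm10 genome, and DESeq2 1.38.3 is also named there. The design text of the series names RNAseqChef for the authors' own differential expression. The tool that made the estimated counts, its strand setting and its gene annotation are not given in the sources used here. Reads of overlapping genes on opposite strands and of near-identical paralogs may therefore have been shared, and some are named as uncertain beside their values. Of the 146 named genes, 23 have more than 10% of their exonic bases inside another gene. On the same strand these are Rmrp (96.4%, with another entry of its own symbol), Ctla2b and Itgam (68.7% each), Ctsd (34.4%), Fdps (26.7%), Rpl32 (14.5%) and Tm7sf2 (12.1%). Shares on the opposite strand include those of Tagln (67.9%), Rpl35 (66.2%), Hes5 (31.8%), Bnip3 (22.3%), Nefm (19.2%), Cryab (17.0%), Ina (14.1%), Grin1 (13.5%), Ctsb (12.8%), Bcas1 (12.6%) and Aldh1l1 (11.1%).

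Each column was matched to its sample by name, and groups were taken from the sample titles. Estimated counts were rounded to whole numbers. Analyses were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by the default rule of edgeR's filterByExpr on the group, which removed 10492 of 24411 genes. The remaining 13919 were normalised by TMM and tested with edgeR's robust quasi-likelihood F-test, two-sided, with the group as the only term and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM are TMM-normalised counts per 1000000 of the library total, and log2 CPM used a prior count of 2. Gene lists were tested with camera on log2 CPM with a preset inter-gene correlation of 0.01, with adjustment over the 32 lists tested. Unless another test is named, a p given for a list is from camera and one given for a gene is from edgeR.

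The test, the 33 gene lists and the rule for naming genes were fixed before the data were examined. The rule named the synuclein genes and the 12 genes with the largest log2 fold change in each direction. The latter had to have an adjusted p under 0.05, a mean of at least 5 CPM, all 3 PFF libraries on one side of all 3 PBS libraries and a symbol that is not a bare model name. It also named up to 4 members of each list, those with the smallest unadjusted p. Other genes are said to have been named after their values were seen. The list of mitochondrially encoded protein genes had 0 members in the table, so it was not tested. Of the symbols in the table, 99.6% matched a RefSeq symbol or synonym, and gene coordinates, biotypes and exon overlaps came from GENCODE vM21 (GRCm38, the same assembly as mm10).

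Library totals ranged from 9224974 to 10742383 counts, the common dispersion was 0.00642, and the depth behind a gene follows from its CPM and these totals. The steps were tested on simulated data, with counts drawn for the 13919 genes from the means and library sizes of these samples. Of 50 genes changed at each size, 8 were recovered at 1.25-fold, 34 at 1.5-fold, 45 at 2-fold and 49 at 4-fold, with 11 calls among the unchanged genes. Changes of about 1.25-fold were thus mostly missed at this depth and number of libraries.

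Alternatives to the normalisation (DESeq2 size factors, upper quartile, library size only), the low-count filter (none, or at least 50 counts in 3 libraries), the test (DESeq2 1.42.0, limma-voom, edgeR without robust estimation), the threshold, a block on the replicate number and leaving out each library in turn were planned. For the lists, camera with an estimated correlation, camera on ranks and the rotation test fry were planned too. Added after the data were seen were replicates 1 and 2 only, replicate 3 as a batch term, removal of Rn45s, and removal of trends with gene length and GC content of the longest annotated transcript.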

Results

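RNA sequencing was used to compare cortical neuron cultures of mouse that had received preformed fibrils of mouse α-synuclein with cultures that had received phosphate-buffered saline (PBS). Preformed fibrils (PFF) are aggregates of α-synuclein assembled outside the cell and used to seed aggregation of the endogenous protein. The cultures came from the cortex of embryos at day 18. The fibrils were added at 3.45 µM on day 10 in vitro, and RNA was taken on day 18 in vitro, after 8 days of exposure. Each group held 3 libraries, numbered 1 to 3 as in their labels, and the question was which transcripts differed between the groups. The labels name PBS as the only control treatment, so the comparison contains everything that was added with the fibrils. The labels do not say whether the libraries came from separate cultures. The p-values measure only the spread between these samples, which may be technical.

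Total estimated counts ranged from 9224974 to 10742383 per library, with a mean of 10095439 ± 783009 in PBS and 10140435 ± 97796 in PFF (SD, n = 3 each). A count above 0 in at least 1 library was found for 19001 of the 24411 genes, and 13919 genes had enough counts to be tested. The precursor of ribosomal RNA, Rn45s, took 4.76 ± 0.902% of the counts in PBS and 3.55 ± 0.542% in PFF. The first principal component held 49.2% of the variance and separated the groups. The second held 18.3% and separated replicate 3 of both groups (−14.5 for PBS 3 and −18.0 for PFF 3) from the other libraries. No replicate pair agreed within sampling noise: the chi-square per degree of freedom was 2.698 and 2.90 for replicates 1 and 2 of PBS and of PFF, and between 7.18 and 9.196 for pairs that included replicate 3.

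**Figure D1:**
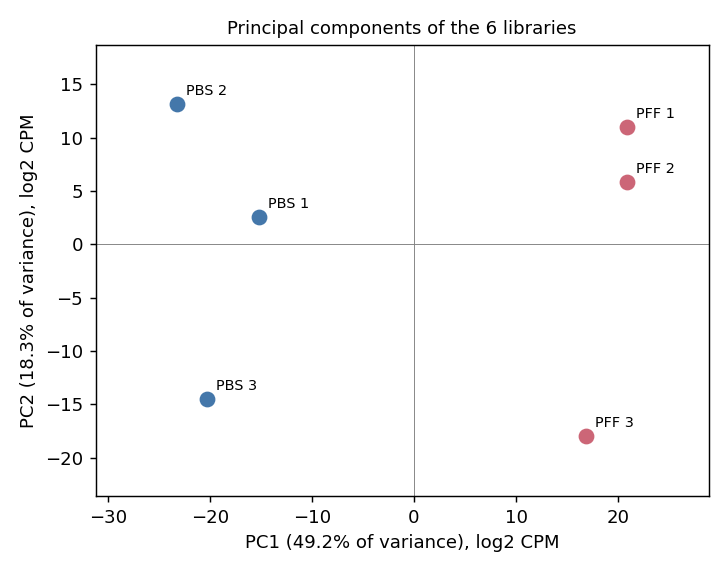
Principal components of log2 CPM over the tested genes, with 1 point per library, PBS in blue and PFF in red. The horizontal axis (49.2% of the variance) parts PBS from PFF, and the vertical axis (18.3%) places PBS 3 at −14.5 and PFF 3 at −18.0, below the other 4 libraries.

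Among genes with a mean of at least 5 CPM (counts per 1000000) and no overlap between the groups, leaving out bare model names, the largest rises after PFF were in Cd36, Anxa1, Mmp12, Pik3ap1, Msr1 and Plau. Cd36, a scavenger receptor for lipids and protein aggregates, rose from 5.91 ± 1.86 to 45.0 ± 4.64 CPM (mean ± SD), a log2 fold change of 2.94 ± 0.16 (SE; n = 3 per group here and below). Anxa1, a phospholipid-binding regulator of inflammation, rose by 2.71 ± 0.27 on the log2 scale, and Mmp12, the macrophage metalloelastase, by 2.45 ± 0.15. Lgals3, which encodes galectin-3, rose from 14.8 ± 3.32 to 68.7 ± 3.38 CPM (2.22 ± 0.12). Next to these stood the signalling adaptor Pik3ap1 (2.41 ± 0.23), the scavenger receptor Msr1 (2.39 ± 0.18), the urokinase gene Plau (2.31 ± 0.14) and the C5a receptor C5ar1 (2.26 ± 0.22). The endosomal receptor Tlr13 (2.20 ± 0.21), the exchange factor Vav1 (2.17 ± 0.26) and the actin-capping gene Capg (2.15 ± 0.16) followed. Ctla2b also rose (2.24 ± 0.18), but its value is uncertain because its near-identical paralog Ctla2a may share its reads. Adjusted p-values of these 12 genes ran from 4.69e-07 (Cd36 and Lgals3) to 0.000189 (Vav1) in edgeR's quasi-likelihood test, and all 3 PFF libraries lay above all 3 PBS libraries for each. In GENCODE vM21 on GRCm38 (mm10), Cd36 lies on chromosome 5 from 17781690 to 17888801, Lgals3 on chromosome 14 from 47367751 to 47386160 and Mmp12 on chromosome 9 from 7344381 to 7369499. All 3 are protein-coding, and their counts are per gene, without exon or transcript detail.

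**Figure D2:**
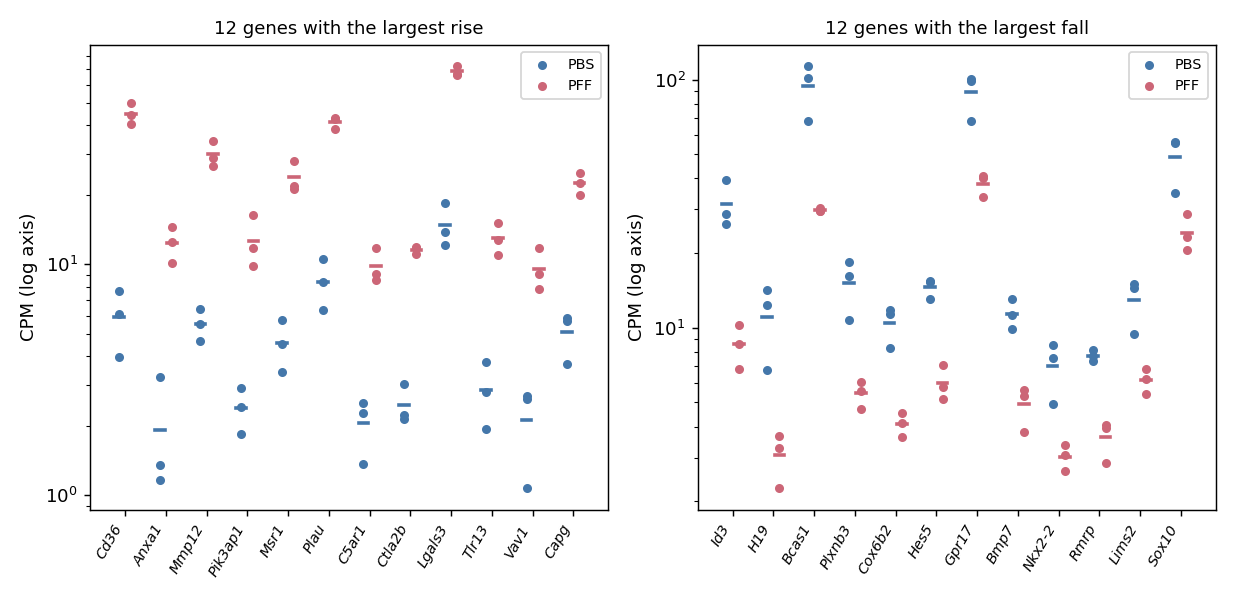
Normalised counts in CPM (log axis) of the 12 genes with the largest rise and the 12 with the largest fall among those meeting the naming rule, with 1 point per library and a bar at each group mean. For Cd36 the PFF mean was 45.0 and the PBS mean 5.91, and in each of the 24 genes the 3 PFF points lie on the same side of the 3 PBS points.

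In total 916 of the 13919 genes changed at an adjusted p under 0.05, of which 554 rose and 362 fell, and 2944 genes had an unadjusted p under 0.05. A log2 fold change of 1 or more was reached by 247 of the genes that rose, and of −1 or less by 34 of those that fell. Because replicate 3 stood apart in both groups, the comparison was also made without replicate 3 and with it as a batch term. Both alternatives were chosen after the data were seen. The labels name no batch, so this grouping came from the values themselves. With replicates 1 and 2 only, 1225 genes rose and 1169 fell, including 852 of the 916. Replicate 3 has 1 library per group and gives no test of its own. Between its libraries, 86.8% of the 1220 genes called higher in replicates 1 and 2 and tested in all libraries were also higher in PFF, against 51.6% of all genes. Likewise 78.7% of the 1165 called lower were lower, against 48.5% of all genes. With replicate 3 as a batch term, 1029 genes rose and 976 fell, including 915 of the 916. The number of changed genes was 511 without PBS 1, 601 without PBS 2, 744 without PBS 3, 581 without PFF 1, 412 without PFF 2 and 1858 without PFF 3.

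Markers of microglia and macrophages rose together. Of the 19 tested members of that list, 17 rose and none fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 1.32. The integrin Itgam rose by 1.89 ± 0.15, from 4.56 ± 0.670 to 16.9 ± 1.08 CPM. Rises followed in the complement gene C1qa (1.56 ± 0.15), the lysosomal membrane gene Laptm5 (1.49 ± 0.15) and cathepsin S (Ctss, 1.42 ± 0.14). Of the exonic bases of Itgam, 68.7% are shared with an overlapping gene model on the same strand. The list's rise had an adjusted p of 2.03e-18 in the set test camera with a preset correlation of 0.01, and an adjusted p = 0.516 with an estimated correlation. Of the 32 tested lists 17 were called in this way, 9 up and 8 down, and no call held with an estimated correlation.

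Other immune and glial reaction genes rose with these markers, whose median was 1.32. In the complement and antigen presentation list 8 of 18 genes rose and none fell (9 and 1 adjusted over the list alone; adjusted p = 7.24e-06, and adjusted p = 0.516 with an estimated correlation). Among them were C1qa, C1qc (1.32 ± 0.16), C4b (0.81 ± 0.12) and C3 (1.91 ± 0.25). The C1q genes stand in both lists. Cytokines, chemokines and NF-kB targets had 5 of 18 genes rise and none fall (6 and 1 adjusted over the list alone; adjusted p = 0.00421, and adjusted p = 0.516 with an estimated correlation). The chemokine genes Ccl4 and Ccl3 rose by 1.55 ± 0.21 and 1.76 ± 0.28. From low levels in PBS, Ccl2 rose by 2.19 ± 0.45 (0.586 ± 0.433 CPM) and Tnf by 1.96 ± 0.43 (0.374 ± 0.145 CPM). Reactive astrocyte genes had 9 of 28 rise and none fall (12 and 0 adjusted over the list alone; adjusted p = 2.21e-06, and adjusted p = 0.573 with an estimated correlation). Serpina3n, a protease inhibitor, rose by 0.77 ± 0.13, the sphingosine receptor gene S1pr3 by 0.69 ± 0.13 and Emp1 by 0.71 ± 0.14. The metalloreductase gene Steap4 rose by 2.60 ± 0.46 from a low level in PBS (0.305 ± 0.120 CPM). The type I interferon list was not called (adjusted p = 0.439), with 2 of 15 genes higher and 1 lower (3 and 2 adjusted over the list alone). Bst2 rose by 1.30 ± 0.23, Oas1a rose by 1.72 ± 0.41 from 0.546 ± 0.293 CPM in PBS, and Mx2 fell by 1.10 ± 0.30. With replicates 1 and 2 only, the complement list had 5 genes higher, and C1qc, C3 and S1pr3 no longer passed (adjusted p = 0.0709, 0.0685 and 0.0868). Without PBS 2 or PFF 2 the cytokine list had 3 genes higher. Tnf did not pass without PBS 2 or PFF 1 (adjusted p up to 0.0656), nor Ccl2 without PFF 2 (0.0630). Oas1a did not pass without PBS 2, PBS 3 or PFF 2 (up to 0.128) and Mx2 without any 1 library except PFF 3 (up to 0.190). In DESeq2, Tnf, Oas1a and Mx2 had adjusted p = 0.0603, 0.0651 and 0.203.

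Genes of the oligodendrocyte lineage moved in both directions. The mature myelin gene Mag, which encodes the myelin-associated glycoprotein, rose by 1.41 ± 0.14 from 8.42 ± 1.00 to 22.4 ± 2.79 CPM. Mobp rose by 1.67 ± 0.20, Mog by 1.35 ± 0.23 and Mbp by 1.29 ± 0.15. Bcas1 and Gpr17, which mark cells between progenitor and myelinating oligodendrocyte, were lower. Bcas1 fell from 94.5 ± 23.8 to 29.9 ± 0.525 CPM (−1.66 ± 0.16), and Gpr17 from 89.2 ± 18.5 to 38.1 ± 4.01 CPM (−1.22 ± 0.14). Enpp6 (−1.03 ± 0.26), the lineage factors Sox10 (−1.01 ± 0.18), Olig2 (−0.41 ± 0.10) and Olig1 (−0.34 ± 0.07), and the progenitor receptors Pdgfra (−0.62 ± 0.07) and Cspg4 (−0.38 ± 0.09) also fell. Members beyond Mag, Bcas1, Mobp and Gpr17 were named after their values were seen, apart from Sox10 and Pdgfra, which other parts of the naming rule gave. In all, 5 of 15 members rose and 8 fell (5 and 9 adjusted over the list alone), and the list was not called as a whole (adjusted p = 0.261), with a median of −0.34 and a mean of −0.01. The number that fell was 4 without PBS 1, 5 without PBS 2 and 4 without PFF 2, and without PBS 3 the list was called down (adjusted p = 0.0438). On GRCm38, Mag lies on chromosome 7 from 30899176 to 30914873, Bcas1 on chromosome 2 from 170346991 to 170427845 and Gpr17 on chromosome 18 from 31942997 to 31949636. Exons of Gpr17 overlap 6.14% of the exonic bases of Lims2 on the opposite strand.

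**Figure D3:**
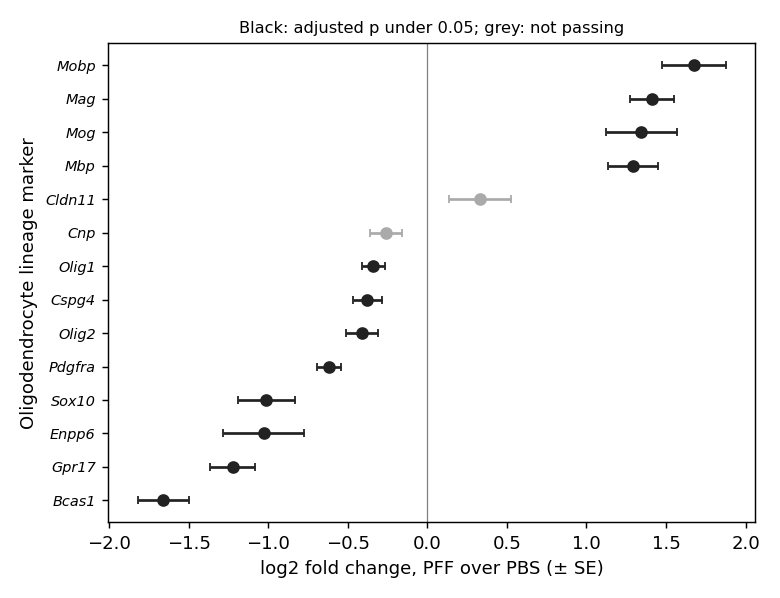
Log2 fold change, PFF over PBS, of 14 of the 15 tested oligodendrocyte lineage markers, with bars of 1 SE either side (3 libraries per group), in black where the adjusted p was under 0.05 and in grey otherwise. Mobp, Mag, Mog and Mbp lie above 0 and Bcas1 lies lowest at −1.66.

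Among the 12 largest falls under the same limits, Id3, an inhibitor of basic helix-loop-helix factors and a target of bone morphogenetic protein signalling, fell from 31.5 ± 6.90 to 8.58 ± 1.72 CPM (−1.87 ± 0.17, adjusted p = 4.01e-05). The imprinted non-coding RNA H19 fell by 1.85 ± 0.28, the semaphorin receptor Plxnb3 by 1.47 ± 0.20, and the testis-type cytochrome oxidase subunit Cox6b2 by 1.35 ± 0.18. The Notch target Hes5 fell by 1.28 ± 0.15, Bmp7 by 1.21 ± 0.18, the homeobox gene Nkx2-2 by 1.20 ± 0.23 and Lims2 by 1.07 ± 0.19. Rmrp fell by 1.09 ± 0.18, but this short non-coding RNA overlaps other annotated genes and its counts are uncertain. Id3 lies on chromosome 4 from 136143497 to 136145755, and H19, a long intergenic non-coding RNA, on chromosome 7 from 142575529 to 142578143. Neural progenitor and proliferation markers had 3 of 17 genes fall and none rise (6 and 0 adjusted over the list alone; adjusted p = 0.000873, and adjusted p = 0.516 with an estimated correlation). These were Hes5, Top2a (−0.36 ± 0.09) and Hes1 (−0.76 ± 0.21). Without PBS 1, PBS 2 or PFF 2, Hes5 alone still passed in that list, and Top2a had an adjusted p of 0.0960, 0.111 and 0.190. Hes1 did not pass without any 1 library except PFF 3 (0.0932 to 0.190), nor in DESeq2 (0.195), and neither gene passed with scaling by library size only (0.0701 and 0.0534).

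Of the astrocyte markers 4 of 18 fell and none rose (4 and 0 adjusted over the list alone; adjusted p = 0.0169, and adjusted p = 0.641 with an estimated correlation). Aldoc, an aldolase, fell from 547 ± 49.6 to 398 ± 32.5 CPM (−0.46 ± 0.09), and the glutamate transporter gene Slc1a2 from 790 ± 134 to 554 ± 6.70 CPM (−0.51 ± 0.10), followed by Aldh1l1 (−0.42 ± 0.11) and Gli3 (−0.60 ± 0.17). The list of endothelial, pericyte and fibroblast markers had 2 of 14 genes fall, Pdgfra and Tagln (−0.78 ± 0.21), and none rise (2 and 0 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.573 with an estimated correlation). Pdgfra, which stands in this list and in the oligodendrocyte list, fell from 126 ± 6.69 to 82.4 ± 3.08 CPM. Extracellular matrix genes were not called as a list (adjusted p = 0.398), with 2 of 25 higher and 3 lower (3 and 6 adjusted over the list alone). Among them were the proteoglycan genes Bcan (−0.63 ± 0.10) and Vcan (−0.59 ± 0.12) and, higher, Timp1 (1.36 ± 0.30) and Fn1 (0.60 ± 0.14). No choroid plexus or ependymal marker of 8 passed (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.187 for the list, and 0.0361 with the stricter low-count filter). The astrocyte count was 1 without PBS 1, 2 without PBS 3 and 0 without PFF 2. The list's call ended without PBS 3, PFF 1 or PFF 2 (adjusted p = 0.265, 0.0563 and 0.0811), as the endothelial list's did without PBS 3 or PFF 2 (0.0999 and 0.0686). Of the genes named here, Bcan and Pdgfra passed with each library left out in turn. Without PFF 2 the others except Fn1 had adjusted p between 0.0557 (Slc1a2) and 0.217 (Gli3), and without PBS 1 the others except Fn1 and Slc1a2 between 0.0530 (Aldoc) and 0.177 (Tagln). Aldh1l1, Gli3, Tagln and Fn1 did not pass without PBS 3 (0.0660 to 0.133), Timp1 and Gli3 without PBS 2 (0.0592 and 0.0542), Aldh1l1 without PFF 1 (0.104), and Gli3 and Tagln without PFF 3 (0.0508 and 0.0555) or with replicates 1 and 2 only (0.0542 and 0.253). Gli3 also did not pass with scaling by library size only (0.0654), the stricter low-count filter (0.0514) or DESeq2 (0.123).

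Genes of cholesterol biosynthesis fell together, and none rose. Of 23 tested genes, 13 fell (17 adjusted over the list alone), with a median log2 fold change of −0.34. Fdps, the farnesyl diphosphate synthase gene on chromosome 3 from 89093588 to 89101959, fell from 149 ± 7.33 to 105 ± 1.85 CPM (−0.51 ± 0.07). The sterol reductase gene Tm7sf2 fell by 0.66 ± 0.10, lanosterol synthase (Lss) by 0.53 ± 0.08, and the sterol carrier gene Stard4 by 0.74 ± 0.11. The list was called with an adjusted p = 1.14e-09, and an adjusted p = 0.516 with an estimated correlation. The number that fell was 8 without PBS 2, 8 without PFF 1 and 7 without PFF 2.

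In the list of the NRF2 oxidative stress response 2 of 20 fell and none rose (6 and 1 adjusted over the list alone; adjusted p = 0.000172, and adjusted p = 0.516 with an estimated correlation). These were the cystine transporter gene Slc7a11, which fell from 59.955 ± 8.16 to 30.9 ± 0.430 CPM (−0.96 ± 0.10), and the sulfiredoxin gene Srxn1 (−0.54 ± 0.07). In the p53 target and apoptosis list 6 of 21 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00372, and adjusted p = 0.516 with an estimated correlation). Eda2r, a receptor of the tumour necrosis factor family, fell by 1.00 ± 0.14, the cyclin gene Ccng1 by 0.53 ± 0.09 and Trp53inp1 by 0.43 ± 0.08. The glycolysis and hypoxia list was not called (adjusted p = 0.0508), with Bnip3 lower (−0.50 ± 0.09) as the only 1 of 24 genes to pass (1 adjusted over the list alone). The number of p53 list genes that fell was 3 without PBS 1, 3 without PFF 1 and 2 without PFF 2, where Trp53inp1 had an adjusted p of 0.0520. The NRF2 list had 5 genes lower without PFF 3 and 6 with replicates 1 and 2 only, and the glycolysis list 2 without PBS 3 and 4 with replicates 1 and 2 only. The glycolysis list was called down by camera on ranks, with the stricter low-count filter, without PBS 3 or PFF 1, in replicates 1 and 2 only and with replicate 3 as a batch term (adjusted p from 0.00643 to 0.0450).

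The list of synuclein family and Parkinson disease genes, with 18 tested members, was not called (adjusted p = 0.333). β-Synuclein (Sncb) did not pass, at 160 ± 5.31 CPM in PBS and 175 ± 10.1 in PFF (0.13 ± 0.07, adjusted p = 0.346). γ-Synuclein (Sncg) had at most 1 count in any library and was not tested. The kinase gene Plk2 had a log2 fold change of 0.35 ± 0.10 (adjusted p = 0.0670).

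Immediate early genes, which neurons induce with electrical activity and immune cells also express, were higher in PFF, with the microglia markers at a median of 1.32 in the same libraries. Of 23 tested genes 12 rose and none fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.51. Arc, a regulator of synaptic strength on chromosome 15 from 74669083 to 74672570, rose from 25.9 ± 2.48 to 51.9 ± 4.78 CPM (1.01 ± 0.10). The transcription factor genes Egr1 and Junb rose by 0.86 ± 0.12 and 0.66 ± 0.10, and the pentraxin gene Nptx2 by 0.66 ± 0.10. The list was called with an adjusted p = 5.21e-09, and an adjusted p = 0.516 with an estimated correlation.

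Smaller changes were seen in genes of calcium handling and GABA signalling. In the calcium list 5 of 33 genes rose and none fell (7 and 1 adjusted over the list alone; adjusted p = 0.00149, and adjusted p = 0.573 with an estimated correlation). Among them were the calbindin gene Calb1 (0.38 ± 0.08), the plasma membrane calcium pump genes Atp2b2 (0.40 ± 0.09) and Atp2b1 (0.39 ± 0.09), and the endoplasmic reticulum pump gene Atp2a2 (0.31 ± 0.08). In the GABA list 3 of 17 rose and none fell (6 and 0 adjusted over the list alone; adjusted p = 0.00403, and adjusted p = 0.588 with an estimated correlation), among them the receptor subunit genes Gabbr2 (0.36 ± 0.09) and Gabra4 (0.27 ± 0.07). Without PBS 1 or without PFF 2, 0 genes of either list passed, with adjusted p of the genes named here up to 0.193 (Atp2a2). Over all genes the number changed also fell in these runs, from 916 to 511 and 412. The lost calls may thus reflect the smaller number of libraries, and the genes named here kept their direction. With length and GC trends removed, Atp2a2 and Gabra4 had adjusted p = 0.0518 and 0.0585. Without PBS 2, and likewise without PFF 1, 2 calcium genes and 1 GABA gene rose, and without PFF 3 these counts were 8 and 6. In replicates 1 and 2 only, 13 and 6 genes rose. The GABA list itself was not called without PBS 1 (adjusted p = 0.0641), whereas the calcium list stayed called with each library left out in turn.

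Synaptic, channel and cytoskeleton lists were not called in the comparison of all libraries. In the presynaptic list 2 of 23 genes rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.139). The vesicular glutamate transporter gene Slc17a6 rose from 42.1 ± 3.08 to 62.1 ± 6.29 CPM (0.56 ± 0.09). Cplx2, a regulator of vesicle fusion, fell from 439 ± 26.8 to 330 ± 13.5 CPM (−0.41 ± 0.08), and Syt1 rose by 0.33 ± 0.09. In the postsynaptic list 1 of 23 rose, the glutamate receptor gene Grin1 (0.35 ± 0.09), and none fell (5 and 1 adjusted over the list alone; adjusted p = 0.0508). Among sodium and potassium channels 1 of 28 rose, Kcnq5 (0.41 ± 0.09), and none fell (1 and 0 adjusted over the list alone; adjusted p = 0.0799). Of the neuronal cytoskeleton genes 3 of 20 rose and none fell (6 and 1 adjusted over the list alone; adjusted p = 0.166), the neurofilament genes Nefm (0.67 ± 0.10), Nefh (0.42 ± 0.11) and Ina (0.28 ± 0.08). Of these genes Slc17a6, Cplx2 and Nefm passed with each library left out in turn. Without PFF 2 the others had adjusted p between 0.0808 (Kcnq5) and 0.274 (Syt1), and without PBS 1 between 0.0747 (Kcnq5) and 0.243 (Syt1). Syt1, Grin1, Nefh and Ina also did not pass without PBS 2 (0.0700 to 0.149), nor Syt1, Nefh and Ina without PFF 1 (0.0659 to 0.148), nor Syt1 without PBS 3 (0.0591) or with DESeq2 size factors (0.0535). Among other normalisations, filters and tests, those that ended a call gave Syt1 up to 0.0627, Ina up to 0.0740 and Nefh 0.0517. In replicates 1 and 2 only, 7 presynaptic, 10 postsynaptic, 10 channel and 6 cytoskeleton genes rose, and the presynaptic, postsynaptic and channel lists were called up (adjusted p = 0.0192, 0.000733 and 0.000983). The same 3 lists were called without PFF 3 (0.0313, 0.00583 and 0.00583), and the postsynaptic and channel lists without PBS 3 (0.0107 and 0.0242) and by camera on ranks (0.0299 each). The postsynaptic list was also called with the stricter low-count filter (0.0432) and scaling by library size only (0.0497).

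Few markers of neuron classes passed. Npy, the gene of neuropeptide Y, fell from 49.8 ± 1.96 to 31.96 ± 1.37 CPM (−0.64 ± 0.08), somatostatin (Sst) from 61.1 ± 4.23 to 39.8 ± 3.96 CPM (−0.62 ± 0.09) and Vip by 0.79 ± 0.19. The interneuron transcription factor gene Maf, which macrophages also express, rose by 0.71 ± 0.16 beside the median of 1.32 of the microglia markers. The interneuron list had 1 of 18 genes higher and 3 lower (1 and 3 adjusted over the list alone) and was not called (adjusted p = 0.576, direction down, mean −0.05, median 0.03). In the neuropeptide and neurotrophic list, which shares Npy, Sst and Vip, 1 of 21 was higher and 3 lower (4 and 5 adjusted over the list alone; adjusted p = 0.855, direction up, mean −0.02, median 0.01). The growth factor gene Igf1 rose from 26.8 ± 0.557 to 60.01 ± 1.90 CPM (1.16 ± 0.08). Excitatory neuron markers had 2 of 17 higher and none lower (2 and 0 adjusted over the list alone; adjusted p = 0.0508), Tbr1 (0.39 ± 0.10) and Mef2c (0.35 ± 0.10). Tbr1 and Mef2c each failed to pass without any 1 library except PFF 3 (adjusted p up to 0.250). In DESeq2, Vip and Tbr1 had adjusted p = 0.103 and 0.0513, and Mef2c had up to 0.0558 under other normalisations, filters or tests. Vip did not pass without PBS 1, PBS 3, PFF 1 or PFF 2 (up to 0.126), and Maf without PBS 1, PFF 1 or PFF 2 (up to 0.0769). The excitatory list was called up by camera on ranks, with the stricter low-count filter, with length and GC trends removed, without PBS 2 or PFF 3, and in replicates 1 and 2 only (adjusted p from 0.0120 to 0.0432).

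Some lysosomal genes rose, with the microglia markers at a median of 1.32 in the same libraries. Of 37 tested lysosome and autophagy genes 9 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 9.31e-05, and adjusted p = 0.573 with an estimated correlation). Cathepsin Z (Ctsz) rose from 26.8 ± 4.66 to 60.4 ± 7.71 CPM (1.18 ± 0.13). Cathepsins D (Ctsd) and B (Ctsb) and the glucuronidase gene Gusb rose by 1.03 ± 0.12, 0.96 ± 0.12 and 0.95 ± 0.12. The gene that fell was Wipi1 (−0.49 ± 0.11), an autophagy gene named after its value was seen. Ctsd lies on chromosome 7 from 142375911 to 142388038, and 34.4% of its exonic bases are shared with another gene model on the same strand. With replicates 1 and 2 only, 14 genes of the list rose and 3 fell. The number that fell was 0 without PBS 1, PFF 1 or PFF 2 and 3 without PFF 3.

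Genes of protein folding stress changed in both directions. In the list of the unfolded protein and integrated stress responses 5 of 24 rose and 2 fell (7 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.259). The stress transcription factor gene Atf3 rose from 8.57 ± 1.11 to 17.2 ± 1.47 CPM (1.01 ± 0.13), the endoplasmic reticulum chaperone genes Calr and Hspa5 rose by 0.43 ± 0.08 and 0.45 ± 0.10, and Psat1, of serine synthesis, fell by 0.49 ± 0.07. Cytosolic heat shock genes had 2 of 16 rise and 1 fall (6 and 2 adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.548 with an estimated correlation). Hsph1 rose by 0.35 ± 0.07, Hspa1b, whose near-identical paralog Hspa1a may share its reads, rose by 0.83 ± 0.23, and Cryab fell by 0.45 ± 0.12. None of 31 proteasome genes passed in edgeR (0 adjusted over the list alone; adjusted p = 0.858 for the list), and Psmb1 came nearest at −0.22 ± 0.08 (adjusted p = 0.146). The number of stress response genes that rose was 1 without PBS 1, 2 without PBS 2 and 1 without PFF 2. Calr did not pass without PBS 1 or PFF 2 (adjusted p = 0.0575 and 0.0558), nor Hspa5 without PBS 1, PBS 2 or PFF 2 (0.0573 to 0.101), nor Hsph1 without PBS 1 or PFF 2 (0.0791 and 0.0665). Cryab did not pass without PBS 1, PBS 3, PFF 1 or PFF 2 (0.0501 to 0.192), and Hspa1b did not pass without any 1 library (0.0750 to 0.169), in DESeq2 (0.226) or in limma-voom (0.0544). Cryab also missed the threshold with scaling by library size only (0.0563) and with length and GC trends removed (0.0544). The heat shock list was not called without PBS 1, PBS 2 or PFF 2 (adjusted p = 0.0540, 0.0651 and 0.0931), and 4 proteasome genes fell with replicates 1 and 2 only.

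Ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower in 2 of the 3 PFF libraries. Averaged over the ribosomal protein list, PFF 1 and PFF 2 lay −0.41 and −0.36 from the PBS mean on the log2 scale, and PFF 3 lay at 0.06. For oxidative phosphorylation these values were −0.40, −0.31 and 0.03. PBS 3 lay at −0.03 and 0.11 in the 2 lists. In the comparison of all libraries 2 of 40 ribosomal protein genes fell and none rose (0 adjusted over the list alone; adjusted p = 8.02e-07, and adjusted p = 0.610 with an estimated correlation), Rpl35 (−0.36 ± 0.10) and Rps24 (−0.45 ± 0.12). Of 46 oxidative phosphorylation genes 1 fell, Uqcrq (−0.43 ± 0.11), and none rose (0 adjusted over the list alone; adjusted p = 8.80e-07, and adjusted p = 0.629 with an estimated correlation). With replicates 1 and 2 only, 39 of the 40 ribosomal protein genes and 32 of the 46 oxidative phosphorylation genes fell, without PFF 3 alone 37 and 32 did, and with replicate 3 as a batch term 16 and 27 did. The ribosomal count was 0 without PBS 1, PBS 2, PFF 1 or PFF 2 and 4 without PBS 3. The oxidative phosphorylation count was 0 without PBS 1, PBS 3, PFF 1 or PFF 2, where Uqcrq had adjusted p between 0.0757 and 0.174. Rpl35 and Rps24 did not pass without any 1 library except PFF 3 (adjusted p from 0.0684 to 0.231), nor Rps24 with the stricter low-count filter (0.0543).

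**Figure D4:**
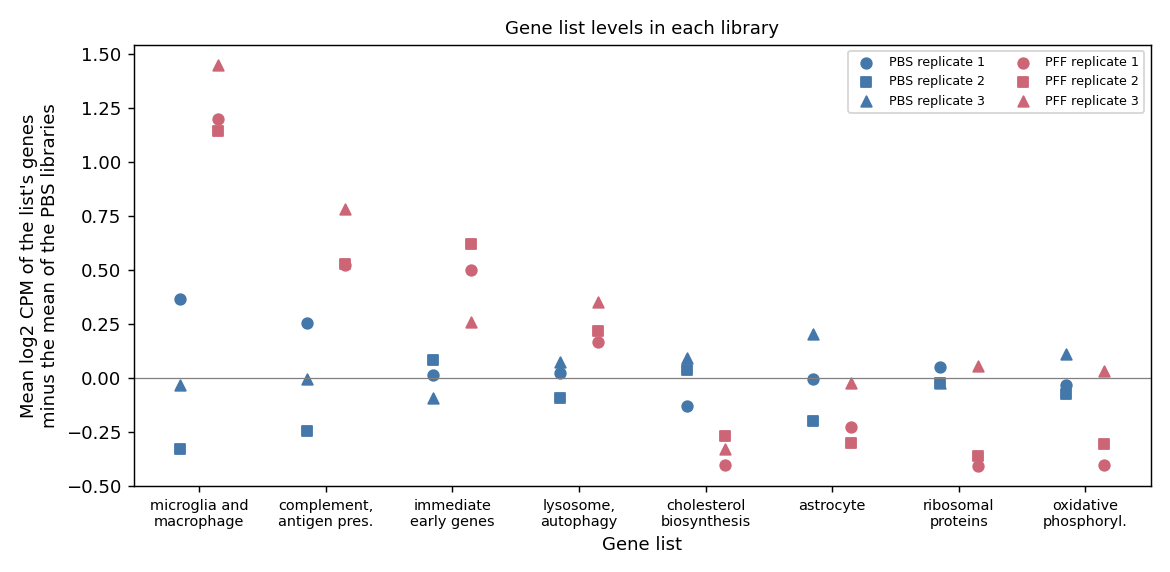
Mean log2 CPM of the genes of 8 lists in each library, minus the mean of the PBS libraries, with PBS in blue, PFF in red and a marker shape per replicate number. In the microglia list the PFF libraries lie at 1.20, 1.15 and 1.45, and in the ribosomal protein and oxidative phosphorylation lists PFF 3 lies at 0.06 and 0.03, apart from the other PFF libraries.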

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

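Removal of Rn45s, removal of length and GC trends, replicates 1 and 2 only and replicate 3 as a batch term were chosen after seeing the data, and the other alternatives were planned. The number of changed genes (916; 554 higher, 362 lower) stayed between 694 and 1132 under 3 other normalisations, 2 other low-count filters, DESeq2, limma-voom, edgeR without robust estimation, removal of Rn45s and removal of length and GC trends. A block on the replicate number gave 1997 changed genes (1043 higher, 954 lower), although same-number libraries were not closest throughout: their correlations of residuals were 0.0919, 0.109 and 0.202, and PBS 2 lay nearer to PFF 1 (0.128). Replicates 1 and 2 only gave 2394 (1225 and 1169), and replicate 3 as a batch term 2005 (1029 and 976); the cause was not tested. An adjusted p under 0.01 left 414 genes (291 and 123), and an absolute log2 fold change of at least 1 left 281 (247 and 34), both by stricter thresholds. Leaving out each library in turn gave 412 to 1858 changed, 312 to 871 higher and 100 to 987 lower, the lowest without PFF 2 and the highest without PFF 3, and 14 to 21 lists. Of the 17 called lists, 0 were called with an estimated correlation. Fry called 3 lists (adjusted p = 0.0390 each), of which 2 are among the 17 (microglia and p53) and that of synuclein genes is not; the cause was not tested. The other list alternatives called 17 to 22. Of the 108 named genes that passed, 64 passed under every alternative run, 44 were lost under at least 1 (39 without PFF 2, 34 without PBS 1), and 0 of the 146 named genes reversed. Removal of mitochondrially encoded genes was not run because the table holds 0 of them. In simulated data of this depth 8 of 50 genes at the smallest fold tried were recovered, so small changes were mostly missed.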

Other observations

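The gene groups in the next 2 paragraphs, the splits of the libraries, and the tests of microglia share and of lower oligodendrocyte yield were chosen after the result was seen. The tests of normalisation, of length and GC content and of oligodendrocyte stage were written before.

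Of 12 tested genes of fatty acid synthesis and desaturation, 6 fell after PFF, 6 did not pass and none rose. These groups were given no set test. The desaturase gene Scd1 fell from 587 ± 44.9 to 318 ± 22.98 CPM (SD, n = 3; log2 fold change −0.88 ± 0.09, SE). Acss2 (−0.66 ± 0.09), Fads2 (−0.61 ± 0.11), Fads1 (−0.42 ± 0.09), Acaca (−0.41 ± 0.08) and the fatty acid synthase gene Fasn (−0.33 ± 0.07) also fell. Of 10 genes of serine, glycine and one-carbon metabolism 4 fell and none rose: Cth (−1.05 ± 0.18), Aldh1l2 (−0.61 ± 0.10), Psat1 (−0.49 ± 0.07) and Phgdh (−0.41 ± 0.09). The number of fatty acid genes that fell was 4 without PFF 1, and 10 with a block on the replicate number or with replicate 3 as a batch term, where 7 serine and one-carbon genes fell. Fads1 did not pass without PBS 1, PFF 1 or PFF 2 (adjusted p up to 0.0850), Fasn without PBS 2 or PFF 1 (0.0911 and 0.0656), and Phgdh without PBS 3, PFF 1 or PFF 2 (up to 0.111).

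Among ligands of bone morphogenetic protein signalling and the Id, Hes and Hey genes, 6 of 14 fell and 1 rose. The ligand gene Bmp4 fell by 1.92 ± 0.33, Id1 by 0.91 ± 0.18, and Id3, Bmp7, Hes1 and Hes5 are given with the largest falls above, while Bmp2 rose. Of 16 genes of disease-associated microglia and lipid-laden macrophages 9 rose and none fell. Plin2, a lipid droplet gene, rose from 24.9 ± 8.85 to 105.7 ± 15.2 CPM (2.10 ± 0.21), Spp1 by 1.72 ± 0.19, Lpl by 1.62 ± 0.11, Gpnmb by 1.53 ± 0.16 and Clec7a by 0.94 ± 0.11. In replicates 1 and 2 only, 5 of these rose, 1 fell (Fabp5, −0.33) and Plin2, Spp1, Gpnmb and Lyz2 did not pass (adjusted p = 0.136, 0.148, 0.163 and 0.150). With a block on the replicate number 8 rose, and Gpnmb did not pass (0.0664), and Fabp5 also fell without PFF 3 (−0.29) and with replicate 3 as a batch term (−0.22). Id1 did not pass without PFF 2 (0.0574), Bmp2 without PBS 1, PBS 3 or PFF 2 (up to 0.108), and Hes1 without any 1 library except PFF 3 or in DESeq2 (up to 0.195). The nuclear RNA Neat1 rose from 23.2 ± 2.61 to 46.3 ± 3.72 CPM (1.00 ± 0.10). Malat1 fell by 0.51 ± 0.12 but did not pass without PBS 1, PBS 2 or PFF 2 (up to 0.135).

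The rise of microglia and macrophage markers is not accounted for by the normalisation: under the other normalisations the lowest median log2 fold change of the list was 1.30, against 1.32. A larger share of microglia alone would give every marker 1 common fold. The folds of the markers ranged from 1.20 to 3.72 and differed by more than their standard errors (Cochran's Q over n = 18 markers, chi-square p = 1.12e-11). That difference does not decide, because markers that other cells also express would rise less: against the pooled C1q genes (1.43 on the log2 scale), the highest of 15 members was not higher beyond its error (Bonferroni-adjusted p = 0.0603). A larger share and a change of expression within microglia therefore cannot be told apart, and both may contribute.

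In the oligodendrocyte lineage the mature myelin genes rose and intermediate and progenitor genes fell. That 5 members rose is part of the pattern and no independent test. A yield lowered alike in all cells of the lineage would let none rise, so the rises argue against it as the whole cause. They leave open a lower yield of progenitor and intermediate cells alone. Length or GC content is argued against because 5 still rose and 8 fell with those trends removed. Stage markers outside the fixed lists parted the same way: of 15 progenitor genes 0 rose and 2 fell (median −0.25), and of 10 mature genes 2 rose and none fell (median 0.41). The medians differed by 0.66 (0.658; p = 0.00046 in a permutation test over 100000 permutations of genes, which are not independent replicates). A shift from progenitor toward mature stage is therefore a hypothesis that may fit these values, and whether cell numbers or expression per cell changed stays open.

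Ribosomal protein and oxidative phosphorylation genes were lower in PFF 1 and PFF 2. With trends of gene length and GC content removed, their medians went from −0.23 to −0.17 and from −0.21 to −0.15 (−0.154). The standard errors of the medians after removal were 0.0153 for ribosomal and 0.0117 for oxidative phosphorylation genes. They came from resampling the genes of each list, which are not independent replicates, so they leave out the spread between libraries. The trends as modelled thus left a fall in the medians, and they could account for part of it. Whether length or GC content is the whole cause is not decided. The trends used the longest annotated transcript of each gene, and the expressed transcripts may differ in length. PFF 3 lay at 0.06 and 0.03 and PBS 3 at −0.03 and 0.11 from the PBS mean, so within replicate 3 PFF was lower for oxidative phosphorylation but not for ribosomal genes. With 1 library per group there, a batch and a differing response of those cultures cannot be told apart, and no biological explanation was tested.

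The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone (1 of 10) gave as many changed genes, genes higher, genes lower or called lists. It gave 916, 554, 362 and 17, and the highest of the other splits gave 0, 0, 0 and 15. Every other split mixed PBS and PFF libraries, which puts the difference between them into the spread within groups. The 0 changed genes there therefore say nothing about chance. The 15 lists came from PBS 1, PBS 3 and PFF 3 against the rest. That split set mostly PBS against mostly PFF libraries, so part of the real difference may lie in its calls. Neither the 15 nor the 17 lists therefore show how often the preset correlation calls a list without such a difference.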
